A study of Homo sapiens with 9 samples.

How the data were processed

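The data were 9 one-colour Affymetrix HG-U133A arrays of MCF-7 cells, 3 for each of empty dendrimer, E2 and EDC, all after 4 h. Per the labels' protocols, the cells were treated in phenol red-free medium with stripped serum, and biotin-labelled cRNA was made from 10 ug of total RNA. Each array was placed in its group from its own description in the labels, and replicate numbers were given in accession order, so they pair no arrays across groups. The values used were the deposited intensity per probe set, 1 column per array. They were all above 0, strongly right-skewed and linear, not log values. The arrays had similar medians and upper quartiles. Whether and how the authors normalized the deposited values between arrays, the summary method, the background correction and the software were not given in the sources used here. No scanner files were used here. No pair of arrays held identical values.

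Of 22283 probe sets, 68 controls were left out, which left 22215. Gene names came from the platform annotation supplied with the values, and were looked up through gene identifiers in a RefSeq gene table (assembly GRCh38.p14), used for names only. Of the 22215 probe sets, 19065 had 1 gene symbol, 1043 several and 2107 none, 19053 of the first kind were found in the RefSeq table and no symbol changed. No coordinates are given, because no genome build is named for these values. Genes were named only from probe sets with 1 symbol. A gene with several probe sets was represented by the one with the highest mean.

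Values were analysed as log2(intensity + 16), with no further normalization, so a fold change is on that scale and understates the change of dim probe sets. The upper 60% of probe sets by mean over all 9 arrays were tested, 13329 in number with a mean of at least 4.51 on the log2 scale, or an intensity of about 6.8. They covered 8047 genes. A model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), so that the 3 groups shared 1 estimate of the spread, with 6 residual degrees of freedom and 1.22 from the prior. The tests were two-sided. A probe set was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and 3 comparisons were made. Errors on log2 changes are standard errors of the model, and errors on intensities are SDs of 3 arrays. The number of arrays limits the precision, and array intensities carry no count from which a further interval could be made.

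The design, the filter, the tests, the alternatives, the named genes and the gene lists were chosen before the data were examined. The 27 lists were estrogen-induced and estrogen-repressed genes, immediate early genes, MAPK output, replication and S-phase entry, mitosis, ribosome biogenesis, tRNA synthetases, cholesterol synthesis, the unfolded protein response, heat shock chaperones, the BCL2 family, growth factors and their receptors, nuclear receptors and coregulators, interferon response, NF-kB and inflammation, AHR targets, hypoxia and glycolysis, NRF2 and oxidative stress, p53 targets, TGF-beta, BMP and SMAD signaling, lysosome and endosome, Krueppel, FOX and related transcription factors, and luminal epithelial, basal epithelial, fibroblast or mesenchymal, and immune markers. They held 531 distinct genes, of which 395 were tested, and some genes were in several lists. Lists with at least 5 tested genes, 25 in number, were tested with limma's camera with its preset correlation of 0.01, which compares a list with the other genes, and again with a correlation estimated from the residuals. The fry test was run beside it, and its p asks whether the genes of a list move, on balance, one way, without comparing them with other genes. Counts adjusted over the list alone use the p-values of the same fit.

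Genes named in the text were, for each comparison, the 10 largest rises and 10 largest falls among called probe sets with 1 symbol in which all 3 arrays of one group lay beyond all 3 of the other, up to 3 called members of each list by size of change, and the 10 fixed genes GREB1, TFF1, PGR, MYC, CCND1, ESR1, CXCL12, EGR3, PDZK1 and TSKU. Further members of the lists, given as examples beside counts, and any gene outside this rule were chosen after their values were seen.

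The code was tested on simulated data made from 13329 probe sets, with 67 changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in each comparison. For E2 against empty dendrimer it recovered 67.2%, 83.6% and 98.5% of these, and 13.1% of the calls were false. For EDC against empty dendrimer the recovered shares were 65.7%, 82.1% and 100%, with 7.3% of calls false, and for E2 against EDC 65.7%, 89.6% and 98.5%, with 7.65% false. A list shifted by 0.3 was recovered, and none of the other lists was called. The noise was drawn independently for each probe set, with nothing shared between the probe sets of an array. These rates and the list result therefore do not show how the tests perform where probe sets vary together.

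The alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, the upper 40% of probe sets, a trended and robust variance prior, array weights, only the 6 arrays compared, a minimum fold of 1.5, averages of the probe sets of a gene, and leaving out each array in turn. After the data were examined 2 were added, the GAPDH 5' minus 3' log2 difference as a covariate, and leaving out the 1516 tested probe sets in which arrays of a group held exactly equal values.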

Results

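Expression was measured in MCF-7 cells, an estrogen receptor-positive line derived from a human breast adenocarcinoma, on 9 Affymetrix HG-U133A arrays. The cells had been exposed for 4 h to an empty dendrimer (3 arrays), to the estrogen E2, estradiol (3 arrays), or to an estrogen dendrimer conjugate, EDC, in which the estrogen is attached to a dendrimer, a large branched polymer (3 arrays). The series title names nuclear and extranuclear inputs to gene regulation by estrogen receptors. EDC was made to act on receptors outside the nucleus, so EDC against empty dendrimer bears on the extranuclear input. E2 against EDC shows where the 2 ligands differ. The labels give no dose for either ligand. The median intensity was between 8.71 and 9.94 on each array, the upper quartile was between 93.5 and 102.3, and arrays of one group correlated at 0.988 to 0.995 over the tested probe sets. The first principal component held 52.5% of the variance, and the 3 E2 arrays scored from 23.3 to 26.3 on it, above the 6 other arrays (-28.9 to 4.07). On the second, with 14.9%, the 3 EDC arrays scored from -14.7 to -10.1, below the 6 other arrays (-6.07 to 14.2). The log2 difference between the 5' and 3' control probe sets of GAPDH, a sign of RNA integrity, averaged -2.64 ± 1.22 in the empty dendrimer arrays, -4.02 ± 1.48 in the E2 arrays and -2.09 ± 2.31 in the EDC arrays (SD, n = 3). In exact two-sided permutation tests p was 0.3 for E2 and 0.9 for EDC against empty dendrimer, and 0.3 for E2 against EDC. With 3 arrays against 3, such an exact test cannot give a p below 0.1. GAPDH values of single arrays ran from -5.07 (E2 replicate 2) to -0.308 (EDC replicate 1). For ACTB the same difference ran from -9.23 (E2 replicate 3) to -4.12 (EDC replicate 1). The 5' BioB control had intensities of 258 to 378 in EDC arrays. It had 396 to 1027 in empty dendrimer arrays and 312 to 1569 in E2 arrays. These controls thus varied widely between arrays, and ACTB and BioB were not used as covariates.

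The first comparison asked which transcripts free E2 changed within 4 h. E2 raised classical estrogen-responsive genes. TFF1, a secreted trefoil peptide, went from an intensity of 15.4 ± 5.04 to 746 ± 676 (SD, n = 3), an 18.9-fold rise (log2 change 4.24 ± 0.56, SE), with E2 arrays at 273, 445 and 1521. CA12, a carbonic anhydrase, rose from 137 to 1689.6 (log2 change 3.47 ± 0.15), the receptor tyrosine kinase gene RET from 16.1 to 242 (8.01-fold) and IGFBP4, which binds insulin-like growth factors, from 86.3 to 640 (2.68 ± 0.16). The homeobox genes HOXC6 and HOXC4 rose by 3.58 ± 0.20 and 3.10 ± 0.16 on the log2 scale, and SERPINB9, P2RY2, KAZN and FZD7 were the other 4 of the 10 largest rises, at 2.56 to 3.03. The largest falls were in MMD (-2.74 ± 0.16), ARID5B (-2.41 ± 0.17), the growth factor gene TGFB2 (-2.20 ± 0.26), the prolyl hydroxylase gene EGLN3 (-2.18 ± 0.14) and CCNG2, a cyclin G gene (-2.15 ± 0.13). They were followed by CALD1, ID2, BLNK, FAM13A and ASPM at -2.14 to -1.92. The ASPM call was lost without empty dendrimer replicate 2 or E2 replicate 1, with an adjusted p of up to 0.0578.

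Of the 32 tested genes in the list of estrogen-induced genes, 26 rose and none fell, with a median log2 change of 1.54, and 30 rose when adjusted over the list alone. The cyclin gene CCND1 rose 2.27-fold (1.18 ± 0.08), MYC 1.93-fold (0.95 ± 0.08), GREB1 4.15-fold (2.05 ± 0.25), the chemokine gene CXCL12 3.03-fold (1.60 ± 0.09) and TSKU, a fixed gene outside the list, 4.45-fold (2.15 ± 0.08). PGR and PDZK1 lay below the level needed for testing, with mean intensities of 4.85 and 5.16 after empty dendrimer and 9.94 and 8.96 after E2. Of 20 estrogen-repressed genes, 9 fell, BCL6 rose by 1.10 on the log2 scale and 10 did not pass, and 10 fell and 1 rose when adjusted over the list alone. The estrogen receptor gene ESR1 was among those that fell (-0.52 ± 0.09). Its call was lost without empty dendrimer replicate 2, E2 replicate 1 or E2 replicate 3 (adjusted p up to 0.0634) and when the probe sets of a gene were averaged (adjusted p = 0.311).

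Of 17 genes of TGF-beta, BMP and SMAD signaling 8 fell, none rose and 9 did not pass (9 fell when adjusted over the list alone). The inhibitors of DNA binding ID2 (-2.11 ± 0.13), ID3 (-1.55 ± 0.25) and ID1 (-1.34) were among them, with the signal transducer SMAD3 (-1.01) and the receptor gene TGFBR2 (-0.97), while TGFB1 and SMAD7 had log2 changes of 0.01 and 0.02. Of 26 ribosome biogenesis genes, 7 rose and none fell (8 rose adjusted over the list alone), with the RNA helicase gene DDX10 at 1.25 ± 0.24 and NOP16 at 0.75 ± 0.15. The 7 rises became 2 to 6 without 1 array, with 2 without empty dendrimer replicate 2. Leaving out 1 array at a time, DDX10 was called in 6 of 9 fits (adjusted p up to 0.0671, lost without empty dendrimer replicate 1 or 2 or E2 replicate 2). NOP16 was called in 5 of 9 (up to 0.0838, lost without any empty dendrimer array or E2 replicate 1). Of 22 lysosome and endosome genes 3 rose, namely the cholesterol transporter gene NPC1 (1.12 ± 0.10), the protease gene CTSD (0.86 ± 0.18) and LAMP1 (0.47 ± 0.10). None fell, against 5 that rose and 2 that fell when adjusted over the list alone. The call of the lysosome and endosome list was lost without empty dendrimer replicate 2, with an adjusted p of 0.0505. The calls of ID3 (0.0543), CTSD (0.102) and LAMP1 (0.1) were also lost without that array. CTSD was called in 2 and LAMP1 in 3 of the 9 fits without 1 array, and each was lost without empty dendrimer replicate 1, E2 replicate 1, E2 replicate 3 or EDC replicate 1. CTSD was also lost without EDC replicate 2 or 3, and LAMP1 without E2 replicate 2.

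Some of the other lists held called genes in both directions, and others in 1 direction or none. Among 23 immediate early genes 7 rose and 3 fell (7 and 4 adjusted over the list alone), with FOS at 2.52 ± 0.07 and EGR3 at 1.69 ± 0.14 against KLF6 at -1.15. Among 18 hypoxia and glycolysis genes 5 rose and 4 fell (5 and 4 adjusted over the list alone), with the glucose transporter gene SLC2A1 at 1.59 ± 0.14 against EGLN3 and DDIT4 (-1.38 ± 0.18). Among 20 Krueppel, FOX and related transcription factors 6 rose and 3 fell (6 and 4 adjusted over the list alone), with MYB at 1.75 ± 0.13 and KLF4 at 1.15 ± 0.11 against HEY1 at -1.36 ± 0.14. In the BCL2 family 2 of 12 rose, namely PMAIP1 (1.92 ± 0.15) and BCL2 itself (1.09 ± 0.16), and 2 fell, including BIK (-1.13 ± 0.17), with 2 and 2 also when adjusted over the list alone. Nuclear receptors and coregulators had 3 rises and 3 falls among 14 genes (3 and 4 adjusted over the list alone), with RARA 2.83-fold higher and NRIP1 at 1.57 ± 0.13 against NCOA2 at -1.52 ± 0.18. Cholesterol synthesis had 1 rise (DHCR7, 1.03 ± 0.14) and 2 falls among 16, including SC5D (-1.01 ± 0.12), against 5 and 3 adjusted over the list alone. Of 17 growth factors and receptors 2 rose (1 to 3 without 1 array), and of 11 MAPK output genes 2 rose and 2 fell. Of 32 genes of replication and S-phase entry 2 rose (CDC25A and GINS2) and 1 fell (CCNE2), and of 26 mitosis genes 3 fell (KIF11, TTK and BUB1B). CDC25A and KIF11 were called in each of the 9 fits without 1 array. GINS2 was called in 5 (adjusted p up to 0.0783, lost without empty dendrimer replicate 1 or 2 or E2 replicate 2 or 3) and CCNE2 in 5 (up to 0.0792, lost without empty dendrimer replicate 1 or 2 or E2 replicate 1 or 2). BUB1B was called in 3 (up to 0.113) and TTK in 2 (up to 0.114), each lost without empty dendrimer replicate 1 or 2, any E2 array or EDC replicate 1, and TTK also without EDC replicate 3. Of 14 tRNA synthetases 2 passed upward, FARSA and YARS1, and each was called in 1 of 9 fits without 1 array (adjusted p up to 0.124 and 0.0958). FARSA was kept only without E2 replicate 2 and YARS1 only without EDC replicate 2. Of 19 genes of the unfolded protein response 2 rose, XBP1, called in 9 of 9 such fits, and DNAJB9, called in 1 (up to 0.126), the one without E2 replicate 2. Of 14 heat shock chaperones 2 rose and 1 fell (HSP90AA1, called in 2 of 9 fits, adjusted p up to 0.143). Of 5 AHR targets 1 rose (TIPARP, called in 4 of 9 fits, up to 0.0897) and 1 fell (CYP1A1, -1.49 ± 0.18). Of 11 NRF2 and oxidative stress genes 1 fell (TXNRD1, -1.35 ± 0.16), and 4 of 14 p53 targets fell. The p53 falls were 0 to 3 without 1 array, with 0 without empty dendrimer replicate 2. The 3 immediate early falls became 1 without empty dendrimer replicate 2 or E2 replicate 2. The 5 hypoxia rises became 3 without any of 6 arrays. Without empty dendrimer replicate 2 or E2 replicate 1, among others, there was 1 fall each in the MAPK output, BCL2, cholesterol, nuclear receptor and luminal lists. None of 10 interferon or 9 NF-kB genes passed. Adjusted over the list alone, the rises and falls in these lists were 2 and 0 for growth factors, 2 and 2 for MAPK output, 3 and 3 for replication, 0 and 3 for mitosis and 4 and 1 for tRNA synthetases. They were 2 and 0 for the unfolded protein response, 2 and 2 for chaperones, 1 and 4 for AHR targets, 0 and 1 for NRF2, 1 and 5 for p53 targets and 0 for interferon and NF-kB genes. Of the marker lists, luminal epithelial genes had 2 rises and 2 falls among 15 (3 and 4 adjusted over the list alone), including GATA3 (-0.77 ± 0.07). Fibroblast and mesenchymal genes had 1 rise among 12 on both adjustments, COL5A1 (0.36 ± 0.08), called in 2 of 9 fits without 1 array (adjusted p up to 0.0988). None of 4 basal and 2 immune marker genes passed (1 basal gene fell adjusted over the list alone), and these lists were too short for a list test.

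Over all 13329 tested probe sets, 1155 changed after E2 (limma, Benjamini-Hochberg adjusted), of which 521 rose and 634 fell, and 137 rose and 160 fell by at least 2-fold. In 28.1% of tested probe sets the 3 E2 arrays did not overlap the 3 empty dendrimer arrays, against 10% by chance. For EDC against empty dendrimer, with 14 calls, this share was 34.9%, so it does not follow the number of calls. Where probe sets vary together, 10% is not a firm level. By camera, which compares a list with the other genes, 5 of 25 tested lists were shifted. These were the estrogen-induced genes (adjusted p = 3.09e-30), ribosome biogenesis (adjusted p = 0.000578) and lysosome and endosome (adjusted p = 0.0161) upward, and the estrogen-repressed (adjusted p = 1.88e-06) and TGF-beta genes (adjusted p = 2.66e-05) downward. With an estimated correlation the estrogen-induced, estrogen-repressed and TGF-beta lists held (adjusted p = 0.00878, 0.0229 and 0.0229 with an estimated correlation), and ribosome biogenesis and lysosome and endosome did not (adjusted p = 0.324 for each with an estimated correlation). The estrogen-repressed and TGF-beta lists shared members, among them TGFB2, the lowest value of both (-2.20). Their shifts are therefore not separate results, and the TGF-beta list was not tested without the shared genes. The other 20 lists had adjusted p from 0.154 to 0.937, and in 8 of them median, mean and test differed in sign. The number of changed probe sets was 503 without empty dendrimer replicate 2, 655 without empty dendrimer replicate 1, 619 without E2 replicate 1, 747 without EDC replicate 1, 628 with no filter and 627 with the GAPDH difference as a covariate. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so all p-values given here measure only the spread between these arrays, which may be technical.

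**Figure D1:**
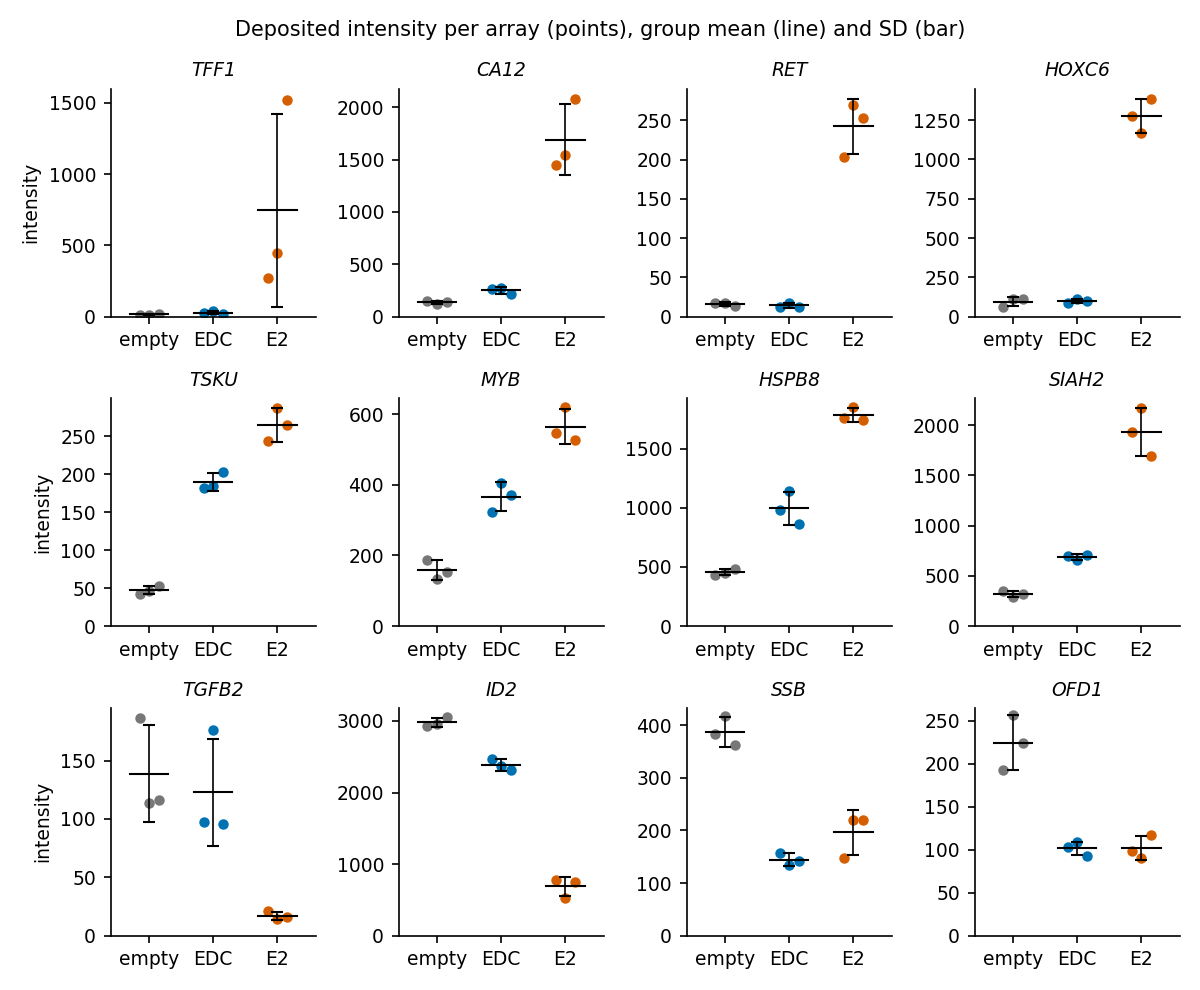
Deposited intensity of 12 genes on each of the 9 arrays, on linear axes from 0. Points are arrays, lines are group means and bars are the SD of 3 arrays. TSKU stood at 47.2 after empty dendrimer, 190 after EDC and 265 after E2, while RET stood at 16.1, 14.3 and 242.

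The second comparison asked which transcripts EDC changed against the empty dendrimer. TSKU, which encodes a secreted leucine-rich repeat protein, went from 47.2 ± 5.27 to 190 ± 11.7 (SD, n = 3), a 3.27-fold rise (log2 change 1.71 ± 0.08, SE, limma adjusted p = 0.00136). The transcription factor gene MYB rose 2.21-fold (1.14 ± 0.13), the small heat shock protein gene HSPB8 2.13-fold (1.09 ± 0.10) and the ubiquitin ligase gene SIAH2 2.07-fold (1.05 ± 0.10). Smaller rises were seen in EMC1 (0.66 ± 0.07), FAM234B (0.52 ± 0.06), the carnitine transporter gene SLC22A5 (0.52 ± 0.06), the splicing factor gene SF3B3 (0.51 ± 0.05) and the adenylyl cyclase gene ADCY9 (0.46 ± 0.05). Falls were seen in SSB, which encodes the La RNA-binding protein (-1.33 ± 0.15), in the centrosomal protein gene OFD1 (-1.03 ± 0.12) and in PDCD10 (-0.54 ± 0.05). The EMC1 rise was in 1 of its 2 tested probe sets, and EMC1 lay outside the rule for named genes and was chosen after its values were seen. The calls of MYB, ADCY9 and SSB were lost when the probe sets of a gene were averaged.

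Of the 32 estrogen-induced genes 4 rose after EDC (MYB, HSPB8, SIAH2 and ADCY9; 0 to 3 without 1 array), none fell and 28 did not pass, with a median log2 change of 0.31, 29 values above 0 and 14 rises when adjusted over the list alone. MYC had a log2 change of 0.56 ± 0.08 (adjusted p = 0.0688) and CCND1 one of 0.31 ± 0.08 (adjusted p = 0.185). For TFF1 the value was 0.48 ± 0.56 (adjusted p = 0.737) and for GREB1 0.65 ± 0.25 (adjusted p = 0.353). None of the estrogen-repressed genes passed (1 fell adjusted over the list alone), nor did any of the 17 TGF-beta genes, whose median log2 change was -0.03, and ESR1 stood at 0.05 ± 0.09 (95% interval -0.16 to 0.26). None of the 22 lysosome and endosome genes passed over all probe sets, 3 rose when adjusted over the list alone, 18 had values above 0 and the median was 0.20, with LAMP1 at 0.47. In the luminal list none of 15 genes passed (2 rose adjusted over the list alone) and in the fibroblast list none of 12 (0 by that adjustment). Among hypoxia and glycolysis genes none of 18 passed (3 rose adjusted over the list alone), among immediate early genes none of 23 (1 rose) and among replication genes none of 32 (0 by that adjustment). In the lists not yet named MYB alone passed, as a member of the Krueppel and FOX list, and at most 3 genes of a list rose and 1 fell when adjusted over the list alone.

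In all, 14 of 13329 tested probe sets changed after EDC, 11 upward and 3 downward (limma), of which 2 had no single gene name, while 1732 had an unadjusted p under 0.05. By camera 5 of 25 lists were shifted, each upward. They were estrogen-induced genes (adjusted p = 2.64e-13), lysosome and endosome (adjusted p = 0.000247), hypoxia and glycolysis (adjusted p = 0.0115), immediate early genes (adjusted p = 0.0281) and replication and S-phase entry (adjusted p = 0.0375). None held with an estimated correlation (adjusted p = 0.0769, 0.15, 0.15, 0.525 and 0.323 with an estimated correlation, in the same order). The other 20 lists had adjusted p from 0.0933 to 0.939, and in 5 of them median, mean and test differed in sign. By fry, which does not compare a list with other genes, 4 lists were shifted, each upward. They were estrogen-induced genes (fry adjusted p = 0.00603), lysosome and endosome (0.0234), hypoxia and glycolysis (0.02) and the Krueppel and FOX list (0.02). By camera without 1 array, the immediate early list was shifted in 6, replication in 5 and hypoxia in 7 of 9 fits, with adjusted p of up to 0.341, 0.29 and 0.0998. Each was lost without EDC replicate 2. The immediate early list was also lost without empty dendrimer replicate 1 or EDC replicate 3, replication without empty dendrimer replicate 2 or 3 or EDC replicate 1, and hypoxia without empty dendrimer replicate 3. TSKU was called in each of the 9 fits that left out 1 array. The other 13 probe sets were called in at most 3 of those fits, and the count was 27 without empty dendrimer replicate 1 and between 1 and 7 without any of the 8 other arrays. The count was 1 with no filter, 7 with the upper 40% of probe sets, 3 with a trended and robust variance prior and 1, TSKU, with the GAPDH difference as a covariate. With that covariate MYB had a log2 change of 1.14 ± 0.14, SIAH2 1.05 ± 0.11, HSPB8 1.08 ± 0.10 and SSB -1.31 ± 0.15, and the adjusted p of the 13 other probe sets was 0.11.

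The third comparison set E2 directly against EDC, after the same 4 h but at doses the labels do not give. E2 gave higher levels of RET (log2 difference 3.09 ± 0.12), HOXC6 (3.51 ± 0.20), HOXC4 (2.98 ± 0.16), SERPINB9 (3.03 ± 0.14), P2RY2 (2.69 ± 0.21), CA12 (2.67 ± 0.15) and the prostaglandin E synthase gene PTGES (2.48 ± 0.31). IGFBP4 and FZD7 followed at 2.36 and 2.29. RET had 242 ± 34.4 after E2 and 14.3 ± 2.83 after EDC (SD, n = 3), and SERPINB9 had 148 and 3.74. TFF1 had 746 and 28.2 (3.76 ± 0.56). The TFF1 call was lost without EDC replicate 1 (adjusted p = 0.0589), with only the 6 arrays compared and with the GAPDH covariate. E2 gave lower levels of MMD (-2.54 ± 0.16), ARID5B (-2.39 ± 0.17), TGFB2 (-2.02 ± 0.26), TMEM131L (-1.87 ± 0.08), EGLN3 (-1.81 ± 0.14) and ID2 (-1.79 ± 0.13). It also gave lower levels of BLNK (-1.75 ± 0.06), GRAMD2B (-1.64 ± 0.12), the corepressor gene BCOR (-1.61 ± 0.16) and PIK3R3 (2.82-fold).

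Of the 32 estrogen-induced genes, 23 were higher after E2 than after EDC and none lower (27 and none adjusted over the list alone), with FOS at 2.24 ± 0.07, CXCL12 at 1.42 ± 0.09 and CCND1 at 0.87 ± 0.08. The 23 became 15 without EDC replicate 1. Of the 20 estrogen-repressed genes 8 were lower after E2 and 1, BCL6, was higher (12 and 1 adjusted over the list alone), and the 8 became 5 without EDC replicate 1. Of the 17 TGF-beta genes 7 were lower (9 adjusted over the list alone), including ID1 (-1.15 ± 0.18), SMAD3 (-1.09) and TGFBR2 (-0.95), and the 7 became 4 without EDC replicate 2. Of the 26 ribosome biogenesis genes 5 were higher (7 adjusted over the list alone), including DDX10 (1.22 ± 0.24) and NOP16 (0.74 ± 0.15). They were called in 2 and 1 of the 9 fits without 1 array (adjusted p up to 0.108 and 0.156), and the 5 became 2 to 4. In the mitosis list 1 of 26 genes passed, KIF11 (-0.59 ± 0.10), 2 were lower adjusted over the list alone and 21 values lay below 0. KIF11 was lost without E2 replicate 2 or any EDC array (adjusted p up to 0.0964) and ID1 without E2 replicate 2 or EDC replicate 2 (up to 0.0666). In the other 20 tested lists at most 6 genes were higher and 3 lower after E2, or 8 and 6 adjusted over the list alone.

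Genes that EDC changed did not all differ between the ligands. HSPB8, SIAH2, SLC22A5 and ADCY9 were higher after E2 (differences of 0.84, 1.47, 1.69 and 1.21), as were TSKU (0.45, 95% interval 0.25 to 0.64) and FAM234B (0.35, 0.20 to 0.49). The TSKU difference was called in 4 of 9 fits without 1 array (adjusted p up to 0.123), and was lost without empty dendrimer replicate 2, E2 replicate 2 or 3, or EDC replicate 1 or 2. EMC1 was lower after E2 than after EDC at the probe set that EDC raised. For MYB the difference was 0.60 (95% interval 0.29 to 0.91) and its adjusted p was 0.0592. No difference passed for SF3B3 (-0.01, 95% interval -0.12 to 0.10), OFD1 (0.00, -0.28 to 0.28), PDCD10 (-0.15, -0.28 to -0.03) or SSB (0.38, 0.04 to 0.73), and for LAMP1 the difference was 0.00 (-0.22 to 0.23).

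In all, 471 probe sets differed between E2 and EDC (limma), 230 higher and 241 lower after E2. By camera 5 of 25 lists were shifted, with estrogen-induced genes (adjusted p = 4.98e-28) and ribosome biogenesis (adjusted p = 0.000992) higher after E2, and estrogen-repressed (adjusted p = 5.58e-07), TGF-beta (adjusted p = 2.82e-06) and mitosis genes (adjusted p = 0.00365) lower. The estrogen-induced, estrogen-repressed and TGF-beta lists held (adjusted p = 0.0108, 0.0149 and 0.0149 with an estimated correlation), and the mitosis and ribosome biogenesis lists did not (adjusted p = 0.0576 and 0.418 with an estimated correlation). Here too the estrogen-repressed and TGF-beta lists shared members, with TGFB2 the lowest value of both (-2.02), so their shifts are not separate results. The other 20 lists had adjusted p from 0.136 to 0.967, and in 5 of them median, mean and test differed in sign. The count was 270 without EDC replicate 1, 280 without EDC replicate 2 and 252 with the GAPDH covariate.

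**Figure D2:**
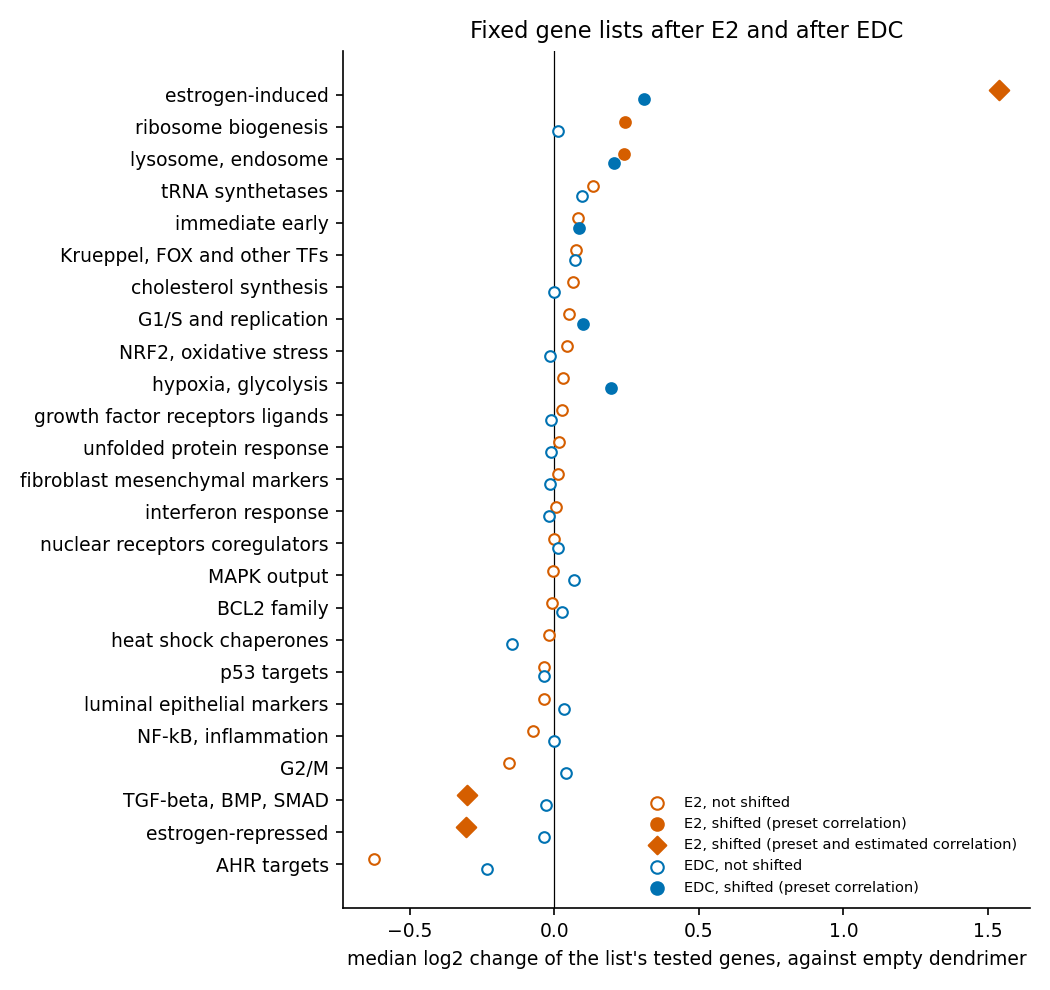
Median log2 change against empty dendrimer of the tested genes of each of 25 fixed lists, after E2 (orange) and after EDC (blue). Filled symbols mark lists shifted by camera with a preset correlation and diamonds those that also held with an estimated correlation. The estrogen-induced list stood at 1.54 after E2 and 0.31 after EDC.

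The responses were then set side by side. Each of the 14 probe sets changed by EDC was also changed by E2 in the same direction, 11 upward and 3 downward, where independent lists would share 0.43 and 0.143. Of the 1155 probe sets changed by E2, 408 also differed between E2 and EDC in the direction of the E2 change, 1 (EMC1) differed in the opposite direction, and 740 (64.1%) passed neither test for EDC. Without EDC replicate 1 or 2 the 408 became 246 and 262. The 740 became 205 (40.8%) without empty dendrimer replicate 2, 294 (44.9%) without empty dendrimer replicate 1, 282 (45.6%) without E2 replicate 1 and 470 (57.0%) without E2 replicate 3, and was at most 1104 (74.6%), without empty dendrimer replicate 3. The largest share was 77.3%, without EDC replicate 2. The 14 shared calls became 1 to 23 without 1 array. A missed threshold does not show a like or an absent response. Among these 740 the 95% interval of the difference between the ligands held 0 in 310, lay on the side of a larger E2 effect in 426 and on the side of a larger EDC effect in 4. These intervals are not adjusted. The 740 were picked for an E2 change, and the same E2 arrays enter the difference. Picking alone can thus shift the intervals towards a larger E2 effect. After EDC, 85.0% of the E2-raised and 86.9% of the E2-lowered probe sets had the sign of the E2 change, and the median ratio of the EDC to the E2 log2 change was 0.325. Picking by the E2 change can also lower this ratio, and no draws were made with an EDC effect equal to that of E2. The ratio was 0.213 without E2 replicate 1 and 0.487 without empty dendrimer replicate 3, the lowest and highest values without 1 array. Both the share and the ratio lay within the range of draws with no EDC change in which whole residual arrays were resampled with replacement. Such a draw could place 1 residual array in several groups, so its range is not that of the shared controls alone. With noise independent between probe sets the share was at most 64.6% and the ratio at most 0.0793. That noise leaves out what the probe sets of an array share, so neither kind of draw decides. With the E2 changes kept, no EDC change and whole arrays of residuals resampled, the ratio averaged 0.0656, 97.5% of 100 draws lay below 0.377 and the highest was 0.536. The share of equal signs, 86.1% over both directions, was 24.7% to 87.9% in 95% of these draws.

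Across the 13329 tested probe sets, which are not independent replicates, the log2 changes after E2 and EDC correlated at 0.568 (Pearson) and 0.513 (Spearman). Both comparisons used the same 3 empty dendrimer arrays. Unchanged groups against shared controls were drawn 100 times by resampling whole arrays of residuals with replacement, so 1 array could stand in several groups. In these draws the correlation averaged 0.466 with 95% of draws between -0.39 and 0.92. The number of shared calls averaged 3.59 and reached 224. The observed covariance was 0.0456 and the simulated one averaged 0.011, a difference of 0.0346, but 95% of the simulated covariances lay between -0.00768 and 0.0402. Only 3 control arrays were at hand, too few to split, so part of the excess may come from the shared controls. Without EDC replicate 3 the correlation was 0.396.

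**Figure D3:**
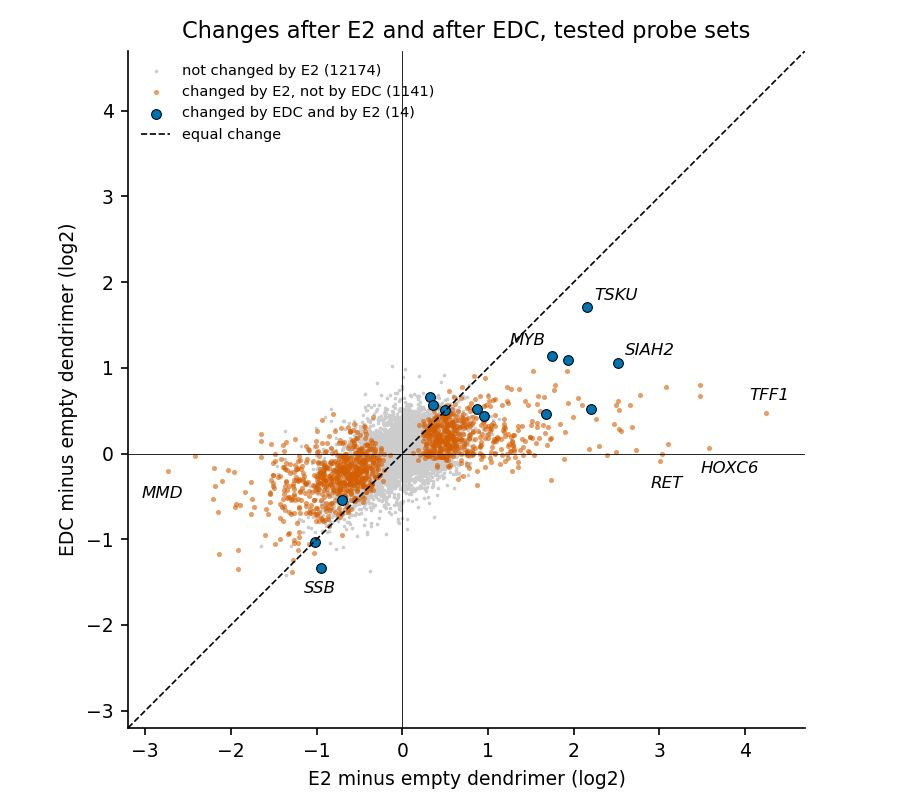
Log2 change after E2 (horizontal) and after EDC (vertical) of the 13329 tested probe sets, each against empty dendrimer. Orange points are probe sets changed by E2 and not by EDC, blue points the 14 changed by both, and the dashed line marks equal change. The median ratio of the EDC to the E2 change was 0.325 in the probe sets changed by E2. Draws with no EDC change and whole residual arrays resampled gave up to 0.377 in 97.5% of draws and 0.536 at most.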

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

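The GAPDH covariate and the omission of probe sets with equal values were chosen after seeing the data. No named gene that was called changed sign under any setting, and 51 of 74 calls of named genes for E2 against empty dendrimer, 1 of 11 for EDC and 39 of 59 for E2 against EDC were kept without any one array. Quantile normalization and median centring left each count of changed probe sets within 1.5 times its value. Which direction held more changed probe sets did depend on the setting. For E2 against empty dendrimer more fell than rose (521 and 634), but more rose with no filter (316 and 312), with the GAPDH covariate (324 of 627 rose) and without E2 replicate 1 (319 and 300) or 2 (457 and 419). For EDC more rose (11 and 3), but 2 rose and 4 fell without E2 replicate 1, and 1 rose and 1 fell without empty dendrimer replicate 2. For E2 against EDC (230 higher and 241 lower) more were higher with quantile normalization (235 and 222), no filter (166 and 150), the covariate (139 and 113) and without any E2 array or EDC replicate 1 or 2, up to 240 and 177 without E2 replicate 2. For E2 against empty dendrimer the count of 1155 was 628 with no filter, 693 with only the 6 arrays compared, 703 with a minimum fold of 1.5, 627 with the GAPDH covariate and 503 to 1479 without 1 array. For EDC the count of 14 was 8 with a pseudocount of 64, 1 with no filter, 7 with the upper 40%, 3 with the trended and robust prior, 7 with a minimum fold of 1.5, 8 with gene averages, 1 with the GAPDH covariate and 1 to 27 without 1 array. For E2 against EDC the count of 471 was 252 with the covariate and 270 to 479 without 1 array. Array weights gave 4988, 1808 and 5175, with 1398 shared calls, 3093 E2-changed probe sets that differed from EDC and a correlation of 0.672, but the weights ran from 0.124 to 21.0 in a fit that did not converge. With the GAPDH covariate the 13 EDC calls that ended had log2 changes near those without it (HSPB8 1.09 and 1.08, SF3B3 0.51 and 0.51) and wider standard errors. A minimum fold is a stricter demand, and the cause of the other differences was not tested. Fits with 6 or 8 arrays hold fewer arrays, but counts also rose in some of them. For E2 the count was 1479 without empty dendrimer replicate 3, and for EDC it was 27 without empty dendrimer replicate 1.

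Shared calls, 14, were 8 with a pseudocount of 64, 1 with no filter, 6 with the upper 40%, 3 with the other prior, 8 with the 6 arrays, 6 with a minimum fold of 1.5, 8 with gene averages, 1 with the covariate and 1 to 23 without 1 array. The E2-changed probe sets that differed from EDC, 408, were 266 with the 6 arrays, 234 with the covariate and 246 to 377 without 1 array. Those that passed neither test for EDC, 740, were 352 with no filter, 422 with the 6 arrays, 426 with a minimum fold of 1.5, 393 with the covariate and 205 to 1104 without 1 array, and the median ratio of 0.325 was 0.482 with array weights and 0.213 to 0.487 without 1 array. The correlation of 0.568 was 0.396 to 0.686 without 1 array. Of the list results, 5 shifted lists became 3 with an estimated correlation and 15 with fry for E2. For EDC they became 3 with quantile normalization, 9 with no filter, 2 with the upper 40%, 0 with an estimated correlation and 4 with fry. For E2 against EDC they became 3 with an estimated correlation and 11 with fry. Without 1 array the shifted lists numbered 4 to 5, 2 to 5 and 5 in the 3 comparisons. No paired analysis was possible because the replicate numbers follow accession order only. Dim probe sets limit all of these values, since the filter stood at an intensity of about 6.8 against array medians of 8.71 to 9.94.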

Other observations

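Beyond the groups described above, HOXC4, HOXC5 and HOXC6 of the HOXC homeobox gene cluster rose after E2, while not all tested genes of the cluster did. HOXC4 and HOXC6 went from 92.1 and 94.6 to 914 and 1273.5, and HOXC5, chosen after its values were seen, rose by 0.93 ± 0.07 on the log2 scale (limma adjusted p = 0.00036, higher in 3 of 3 arrays). HOXC13, also chosen afterwards, fell by 0.82 on the log2 scale (adjusted p = 0.0303), and HOXC11 had a value of -0.08 ± 0.07 (adjusted p = 0.554). After EDC, HOXC4, HOXC5 and HOXC6 had log2 changes of 0.12, -0.01 and 0.07, and each was higher after E2 than after EDC (differences of 2.98, 0.95 and 3.51). None of the tested HOXB and HOXD probe sets was called after E2. These are values, and no explanation for them was tested.

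The tests on shared controls, on RNA integrity and on the groups that do not overlap were chosen only after the results they bear on had been seen. EDC had the sign of the E2 change in 86.1% of the 1155 E2-changed probe sets, with a smaller size in most. Among the 297 changed at least 2-fold by E2, the median ratio of the EDC to the E2 change was 0.24 and 26 (8.75%) departed from it (limma, adjusted over the 297), 11 above and 15 below. Picking by the E2 change can lower this ratio too. A single degree of attenuation was neither borne out (under 5%) nor excluded (at least 10%), and the share was 1.68% to 11.8% without 1 array. It was under 5% without EDC replicate 1 (2.69%), 2 (2.02%) or 3 (1.68%) or empty dendrimer replicate 2 (3.70%), and above 10% only without E2 replicate 2. As examples, all raised by E2, TSKU (ratio 0.793), MYB (0.654) and HSPB8 (0.565) stood above the median ratio and RET (-0.0286) and HOXC6 (0.019) below. They are named because they departed in these same data, so they do not show that EDC acts otherwise than a weaker E2. The shared empty dendrimer arrays remain open as a source of the shared sign. With E2 changes kept and no EDC change, independent noise gave at most 64.6% equal signs. Whole arrays resampled with replacement gave 24.7% to 87.9% in 95% of draws and up to 90.3%, with 4 of 100 draws at or above the observed share. The independent noise leaves out what probe sets of an array share, and the resampled arrays could stand in several groups, so neither decides. A weaker action of the conjugate through the same receptors, a lower dose and free E2 in the EDC preparation were not tested.

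E2 and EDC also differed in 62 probe sets that did not pass the test for E2 against empty dendrimer, some of them narrowly (lowest adjusted p 0.0504), with 49 higher after EDC, and in 58 the E2 and EDC values had opposite signs. Examples chosen after their values were seen were RNF24 (-0.30 after E2 and 0.83 after EDC, difference -1.12 ± 0.14), ZHX2 (-0.36 and 0.55, difference -0.91 ± 0.10) and THBS1 (-0.09 and 0.71, difference -0.80 ± 0.12). RNA integrity stays open as a source: the trend on the GAPDH difference within groups predicted 4.69% of the median difference (1.83% to 10.2% without 1 array), but in probe sets picked for a small spread it could have predicted at most 25.96%, so this test decides nothing. With that covariate 12 of the 62 remained called, while their median difference went from 0.52 to 0.48 and its median standard error from 0.09 to 0.10, so calls ended with a wider error and 1 degree of freedom less. The probe sets were picked from the same data for differing while E2 alone did not pass. Such picking requires the difference to exceed the E2 change. That needs an EDC value of the opposite sign or a larger one of the same sign. The opposite signs therefore follow largely from the rule, and an opposite action of EDC and E2 on these genes was not tested.

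Groups of EDC and empty dendrimer arrays did not overlap in 34.9% of tested probe sets, against 10% by chance, although 14 probe sets were called. The highest share in the other 9 splits of the 6 arrays was 17.9%. A probe set that separates in the real split cannot separate in any other. A high real share therefore lowers the other shares, so they give no independent level for it. Where probe sets vary together, 10% is not a firm level either. The share was 60.5% in the dimmest 4443 probe sets, where the EDC arrays were lower in 58.9% with a median log2 change of only -0.02, and 22.7% in the brightest 4443. Quantile normalization lowered the share to 27.4%, with 21.5% as the highest of the other splits, which are bound to it in the same way. An offset of dim probe sets and array-wide scaling may thus each account for part of the excess, and neither was excluded nor shown to be its whole source.

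The other splits of the 6 arrays in each comparison, 10 with the real one, were too few for a share under 0.05. The real split gave 1155 changed probe sets for E2 against empty dendrimer, 14 for EDC against empty dendrimer and 471 for E2 against EDC, and the highest of the other splits gave 4, 0 and 0, so in each case 1 of 10 splits gave as many. Each other split mixed arrays of both treatments in each group, so any real difference widened the spread and lowered its count. These low counts therefore do not show what chance alone would give.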
